A study of Mus musculus with 12 samples.

How the data were processed

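Poly(A) RNA was sequenced in 12 liver samples from male C57BL/6 mice labelled 8 weeks old, fed chow under 12 h of light and 12 h of dark, per the labels' protocols. The labels place 3 samples in each of 4 groups, wild type (WT) and transgenic with liver-specific E4BP4 overexpression (TG), each at ZT2 and ZT14, where ZT counts hours from lights on. Libraries were made from 850 ng of total RNA with a NEBNext Ultra RNA kit, per the labels' protocols. No label says outright that the samples of a group are separate animals, so p-values measure only the spread between these samples. Pairs within a group differed by a chi-square of 9.85 to 90.89 per degree of freedom, far beyond sampling noise. That argues against repeated sequencing of the same library. Each TG group also held a library that stood apart in many genes, as given below, which argues against 3 repeats of the same liver there. For the WT groups, repeats of the same liver stay open.

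The deposited tables hold 1 set of values per library for 48440 genes, with read counts for whole genes, exons, introns and exon junctions, counts of uniquely mapped reads, and RPKM and TPM values, per the file headers. Total gene reads are the sum of exon and intron reads in every row, and the column called expression value repeats the RPKM. The aligner and its settings, and whether counting used strand, are not given in the sources used here. The submitters' processing notes name the builds mm10 and GRCm38. Of the gene identifiers, 48058 were found in GENCODE M21 for GRCm38, 42135 of them with the same chromosome, start and end and 46103 with the same symbol, and coordinates below are those of the deposited tables. Deposited RPKM and TPM values were not tested, because counts were available.

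The deposited counts of total gene reads were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15, which left 15244 genes. Library sizes were scaled by TMM, and 1 quasi-likelihood model (glmQLFit and glmQLFTest) was fitted to all 12 samples in 4 groups, which share 1 estimate of the spread. Calls are genes with a Benjamini-Hochberg adjusted p below 0.05. The contrasts were TG against WT at ZT2 and at ZT14, ZT14 against ZT2 in WT and in TG, and the interaction, which is the time difference in TG less that in WT. A further contrast, TG against WT averaged over both times, was added after the data were seen. Log2 fold changes are given with their standard error (SE), and expression as CPM (counts scaled to library size) after TMM with the standard deviation (SD) over 3 libraries.

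For each of the 37 gene lists, camera in limma 3.58.1 was run with a preset correlation of 0.01, again with an estimated correlation, and beside fry, with adjustment over the lists within a contrast. With the preset correlation, splits that mix the groups called many lists too, as given at the end, so those adjusted p-values overstate the evidence. Members past the threshold were counted over all genes and adjusted over the list alone. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took Nfil3 and, per pairwise contrast, up to 10 genes in each direction with the largest change among calls whose replicates did not overlap and whose mean was at least 5 CPM in the higher group. Predicted genes and pseudogenes were left out. It also took the 15 interaction genes with the smallest p, the members of the clock, PAR bZIP and D-box output lists, and up to 4 members of every other list with the smallest p. The text names fewer genes than the rule allows, a choice made after their values were seen, and names genes of the averaged contrast and Cadm3 at ZT14 outside the rule. Values of 3 genes the rule takes are not reported here.

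Alternatives were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, no filter beyond 1 read, a filter of 1 CPM in 3 samples, uniquely mapped reads, fits to the 6 samples of a contrast, a replicate block, an adjusted p of 0.01, an absolute log2 fold change of at least 1, and each library left out in turn. Exon reads alone, and the omission of 2 libraries that stood apart, were added after the data were seen.

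The procedure was tested on simulated data, in which 200 genes were changed by known folds, 50 at each size. Genes changed 2-fold were recovered in 64% of cases for TG against WT at ZT2, 72% at ZT14, 62% for time in WT, 62% for time in TG and 34% for the interaction, and genes changed 4-fold in 84%, 90%, 88%, 90% and 72%. Of the simulated calls, 3.55%, 3.40%, 6.94%, 6.43% and 2.00% were genes that had not been changed. The simulation drew each gene independently and held no libraries that stood apart. Where the data give fewer calls than the simulation, as for genotype and the interaction, the adjusted threshold is stricter. The simulated shares may therefore overstate recovery there. Depth was 16035121 to 23981021 total gene reads per library, and no pair of libraries within a group was alike within sampling noise. Genes that overlap each other or belong to families of near-identical copies are treated as uncertain, since the counting could assign their reads to either member.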

Results

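The livers of wild-type mice and of mice carrying a liver-specific E4BP4 transgene were compared at ZT2, early in the light phase, and ZT14, early in the dark phase. E4BP4, encoded by Nfil3, is a bZIP repressor that binds the same D-box elements as the PAR bZIP activators DBP, TEF and HLF, which lie downstream of the circadian clock. Each of the 4 groups had 3 libraries. Total gene reads numbered 22534291, 16035121 and 19703075 in WT at ZT2, 18069468, 17791495 and 18551169 in TG at ZT2, 22026572, 22882899 and 23105370 in WT at ZT14, and 21979960, 23679955 and 23981021 in TG at ZT14. Of these reads 81.2% to 85.5% mapped uniquely and 9.79% to 11.9% lay in introns. On principal components of the 2000 most variable genes, the first component (33.1% of variance) separated the times. The second (16.5%) set TG at ZT2 replicate 2 and TG at ZT14 replicate 3 apart from the other 10 libraries, at -30.8 and -33.2 against 2.0 to 12.1.

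**Figure D1:**
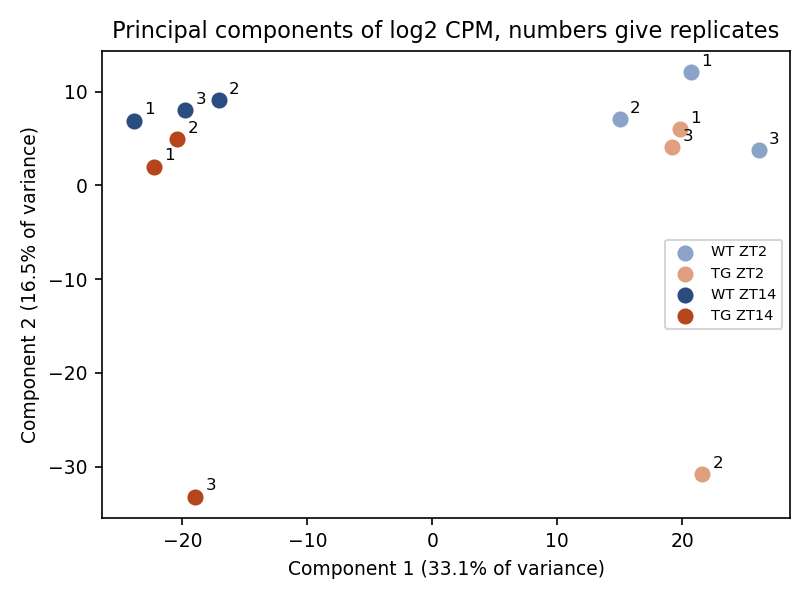
Each point is 1 library on the first (x axis) and second (y axis) principal component of log2 CPM, coloured by group and numbered by replicate. Times separate along the first component, and TG at ZT2 replicate 2 and TG at ZT14 replicate 3 lie at -30.8 and -33.2 on the second.

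Nfil3 (ENSMUSG00000056749, chromosome 13, 52967209 to 52981073) had more reads in every TG library than in any WT library. At ZT2 it averaged 38.6 ± 9.74 CPM in WT and 67.8 ± 4.58 CPM in TG (SD, n = 3 each), and at ZT14 31.1 ± 8.32 and 78.6 ± 15.1 CPM. The log2 fold change was 0.81 (SE 0.21, adjusted p = 0.359 by edgeR's quasi-likelihood test) at ZT2 and 1.34 (SE 0.21, adjusted p = 0.0306) at ZT14. Averaged over both times it was 1.07 (SE 0.15, adjusted p = 0.00942 by edgeR). An exact 2-sided permutation of genotype within each time, chosen after the values were seen, gave p = 0.005, the smallest its 400 relabellings can give. The ZT14 call was lost without any 1 of 8 libraries, WT at ZT2 replicate 3, TG at ZT2 replicates 1, 2 and 3, WT at ZT14 replicates 1 and 3 and TG at ZT14 replicates 2 and 3, with adjusted p = 0.0568 to 0.217 by edgeR.

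At ZT2, TG livers differed from WT in 11 of 15244 genes, 8 higher and 3 lower. The highest fold belonged to Gpr137, an orphan receptor of the lysosomal membrane, which rose 3.80-fold from 17.9 ± 1.70 to 68.0 ± 11.4 CPM (SD, n = 3 each). Its overlapping neighbour Bad, a pro-apoptotic BCL2 family member, rose 2.39-fold from 15.5 ± 0.979 to 37.1 ± 5.22 CPM. Unc13b, a synaptic vesicle priming factor, rose 2.40-fold. Ppard, a nuclear receptor for fatty acids, rose 2.27-fold from 17.3 ± 1.24 to 39.4 ± 5.75 CPM, and Unc5b, a netrin receptor, rose 2.24-fold. Efna1, a ligand of Eph receptors, Chka, a choline kinase of phosphatidylcholine synthesis, and Plcb3, a phospholipase C, rose 1.85-fold, 1.66-fold and 1.40-fold. Prdx5, a peroxiredoxin, Trmt112, an activating subunit of methyltransferases, and Esrra, a nuclear receptor of mitochondrial genes, fell 2.12-fold, 2.22-fold and 2.09-fold.

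By edgeR's quasi-likelihood test, the ZT2 log2 fold changes were 1.92 (SE 0.16, adjusted p = 0.000461) for Gpr137, 1.26 (SE 0.15, adjusted p = 0.0052) for Bad, 1.18 (SE 0.11, adjusted p = 0.000815) for Ppard and -1.08 (SE 0.12, adjusted p = 0.00215) for Prdx5. Gpr137 ran from 1.4 to 2.02 over the alternatives. Trmt112 and Esrra stood at -1.15 and -1.06 (SE 0.11 and 0.10), both with adjusted p = 0.000815. The calls of Bad, Esrra, Gpr137, Ppard, Prdx5 and Trmt112 held in each of the 12 fits that left out 1 library. Without WT at ZT2 replicate 2, Unc13b and Unc5b were lost (adjusted p = 0.0597 and 0.0554), and Efna1 was lost without WT at ZT2 replicates 1 or 2 or TG at ZT2 replicates 1 or 3 (adjusted p = 0.0913 to 0.161). Chka was lost without any library but TG at ZT14 replicate 1 (adjusted p = 0.0535 to 0.308), and Plcb3 without any but TG at ZT14 replicates 1 and 3 (adjusted p = 0.0554 to 0.221). The count was 7 without WT at ZT2 replicate 2, 22 without WT at ZT2 replicate 3 and 9 without the 2 libraries that stood apart. DESeq2 called 57 genes at ZT2 and edgeR without a filter beyond 1 read 43. Gpr137 overlaps Bad, and Trmt112 overlaps both Prdx5 and Esrra on the opposite strand, so reads in the shared parts are uncertain.

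At ZT14, TG livers differed from WT in 13 genes, 7 higher and 6 lower. Gpr137 rose 4.89-fold from 16.2 ± 0.0839 to 79.4 ± 17.0 CPM (SD, n = 3 each). Rps6ka4, a kinase of the histone H3 and CREB response to stress, rose 4.28-fold from 9.93 ± 1.02 to 42.5 ± 14.2 CPM, and Bad 3.68-fold from 13.8 ± 1.71 to 50.7 ± 9.83 CPM. Nfil3, Unc13b and Plcb3 rose 2.53-fold, 2.17-fold and 1.67-fold. Cadm3, a cell adhesion molecule, rose from 0.175 ± 0.0436 to 3.52 ± 1.20 CPM. Among the genes that fell were 3 related N-acetyltransferases of chromosome 6, Nat8 from 13.6 ± 0.929 to 3.83 ± 1.14 CPM, Nat8f6 from 31.1 ± 5.46 to 11.3 ± 2.22 CPM and Nat8f5 from 24.2 ± 6.85 to 8.84 ± 0.439 CPM. Prdx5, Trmt112 and Esrra fell 2.34-fold, 2.13-fold and 1.89-fold.

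By edgeR's quasi-likelihood test, the ZT14 log2 fold changes were 2.29 (SE 0.16, adjusted p = 6.32e-05) for Gpr137, 2.10 (SE 0.22, adjusted p = 0.00104) for Rps6ka4, 4.28 (SE 0.38, adjusted p = 0.000387) for Cadm3, -1.82 (SE 0.21, adjusted p = 0.00167) for Nat8 and -1.47 (SE 0.18, adjusted p = 0.00373) for Nat8f6. Gpr137 ran from 1.65 to 2.46 over the alternatives. Apart from Nfil3, given above, Unc13b was lost without WT at ZT14 replicates 2 or 3 (adjusted p = 0.0509 to 0.0742). Nat8f5 was lost without WT at ZT2 replicate 3, TG at ZT2 replicate 3, WT at ZT14 replicates 1 or 3 or any TG library at ZT14 (adjusted p = 0.0514 to 0.161). Nat8f6 was not called on exon reads alone (adjusted p = 0.132). DESeq2 called 53 genes at ZT14, 22 higher and 31 lower, and edgeR without a filter beyond 1 read 41, 19 higher and 22 lower. Members of the Nat8 family are related copies, so their reads are uncertain, though Nat8 and Nat8f6 stayed called on uniquely mapped reads.

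The times shared 4 higher genes, Bad, Gpr137, Plcb3 and Unc13b, where 0.00367 would be shared by chance (Fisher's exact test, 1-sided, p = 1.09e-12), and 3 lower genes, Esrra, Prdx5 and Trmt112 (0.00118 by chance, p = 3.39e-11). The comparisons used different libraries, and genes are not independent replicates, so these p-values are descriptive. Without WT at ZT2 replicate 2, WT at ZT14 replicate 2 or WT at ZT14 replicate 3, 2 higher genes were shared. Of the 22 genes called for the mean of both times, 17 were higher and 5 lower. Besides those above they included As3mt, an arsenite methyltransferase, at a log2 fold change of 0.52 (SE 0.07, adjusted p = 0.00942 by edgeR), and S1pr5, a sphingosine-1-phosphate receptor, at 0.91 (SE 0.13, adjusted p = 0.0118). The count for the mean was 13 without WT at ZT2 replicate 1 and 12 without the 2 libraries that stood apart, where Nfil3, As3mt and S1pr5 were no longer called, 75 by DESeq2 and 61 by edgeR without a filter beyond 1 read.

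Of the genes shared between times, Unc13b lies on chromosome 4, and the other 6 lie within 140.7 kb of chromosome 19, between 6829085 and 6969759, with Rps6ka4. Along this stretch Rps6ka4 was higher in TG, Prdx5, Trmt112 and Esrra were lower, and Gpr137, Bad and Plcb3 were higher. The other 2 tested genes of the stretch did not pass for the mean of both times, Ccdc88b with a log2 fold change of -0.85 (SE 0.24, adjusted p = 0.381 by edgeR) and the potassium channel gene Kcnk4 with 1.90 (SE 0.42, adjusted p = 0.205).

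**Figure D2:**
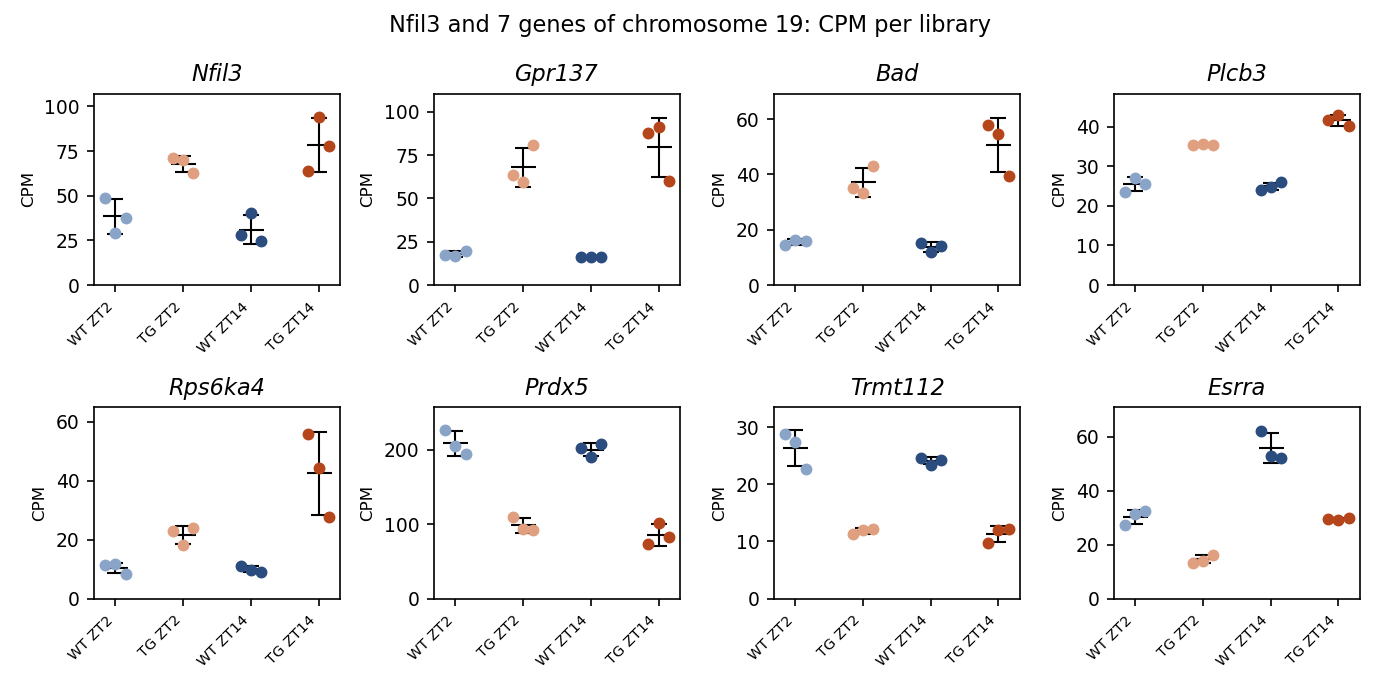
CPM (y axis) of Nfil3 and of 7 genes of chromosome 19 in each library of the 4 groups (x axis), with the mean and SD of 3 libraries as bars. Gpr137 lies at 59.5 CPM or more in every TG library and at 19.8 CPM or less in every WT library.

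**Figure D3:**
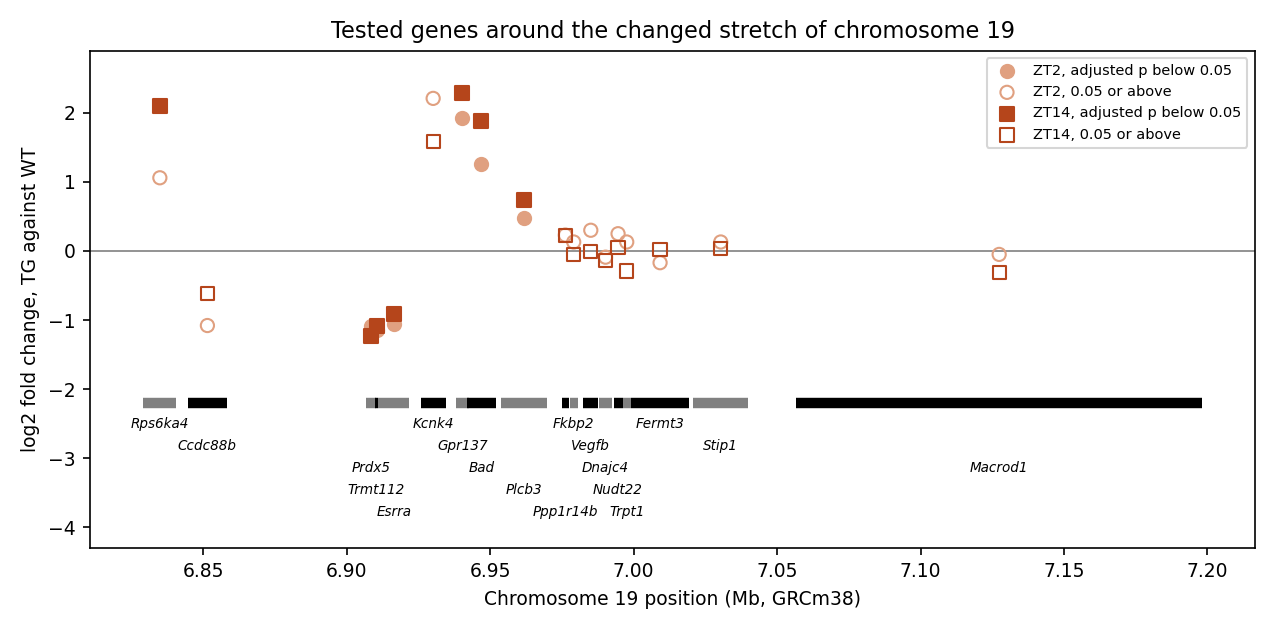
Log2 fold change of TG against WT (y axis) for the tested genes on and around the changed stretch of chromosome 19 (x axis, Mb in GRCm38), at ZT2 (circles) and ZT14 (squares), filled where the adjusted p was below 0.05; bars mark gene bodies. Genes called at either time all lie at or left of Plcb3, which ends at 6969759.

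The clock and D-box genes were examined in TG against WT because E4BP4 is a D-box repressor. Among 36 tested members of the core clock, PAR bZIP and D-box output lists, edgeR called 0 at either time, with 8 at ZT2 and 4 at ZT14 below an unadjusted p of 0.05. Of all 15244 genes, 1153 at ZT2 and 1053 at ZT14 lay below it by edgeR. DESeq2 called 2 at ZT2, Npas2 and Bhlhe41, and 1 at ZT14, Npas2, and limma-voom called 1 and 0. Of the 19 core clock genes, adjusted over the list alone, 1 was higher and 1 lower at ZT2, and 0 higher and 1 lower at ZT14. Fry's test for changes in either direction gave the core clock list adjusted p = 0.00113 at ZT2 and 0.226 at ZT14, while fry in 1 direction called 0 lists at either time. Camera gave the core clock list adjusted p = 0.872 at ZT2, and at ZT14 adjusted p = 0.0154, and adjusted p = 0.595 with an estimated correlation. Npas2, a paralogue of Clock, averaged 8.04 ± 0.788 CPM in WT and 16.1 ± 0.849 CPM in TG at ZT2 (SD, n = 3 each), with a log2 fold change of 1.00 (SE 0.18, adjusted p = 0.103 by edgeR). At ZT14 it averaged 0.483 ± 0.160 CPM in WT and 0.0870 ± 0.0798 CPM in TG, the opposite direction, with -2.43 (SE 0.46, adjusted p = 0.122 by edgeR). At these low counts the ZT14 value ran from -3.37 to -1.51 over the alternatives. Without TG at ZT14 replicate 1, Npas2 was called at both times (adjusted p = 0.0339 and 0.0302). Dbp had a log2 fold change of -1.55 at ZT2, with a large SE of 0.56 (adjusted p = 0.602 by edgeR, and 0.0455 without WT at ZT2 replicate 1). Its ZT2 value ran from -2.07 to -0.88 over the alternatives.

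Over all 37 lists, edgeR called 0 of 725 tested members at either time, with 78 at ZT2 and 108 at ZT14 below an unadjusted p of 0.05, against 1153 and 1053 of all 15244 genes. DESeq2 called 13 and 8 of these members, and limma-voom 1 and 0. At ZT2 the list with the smallest camera p was the 17 stellate cell and fibroblast markers, with a median log2 fold change of 0.40 (camera adjusted p = 2.61e-07, and adjusted p = 0.548 with an estimated correlation). Their mean against the WT mean was 0.41, 0.40 and 0.50 in the 3 TG libraries and -0.20, -0.07 and 0.27 in the 3 WT libraries. At ZT14 the TG libraries stood at 0.34, -0.09 and 0.49. The 12 cholangiocyte markers had a median of 0.42 (camera adjusted p = 0.000155, and adjusted p = 0.591 with an estimated correlation), with 3 higher and 1 lower adjusted over the list alone. By library their mean was 0.63, 0.33 and 0.48 in TG and -0.09, -0.34 and 0.43 in WT, so the groups overlapped. At ZT2 the 22 genes of fatty acid synthesis had a median log2 fold change of 0.29 (camera adjusted p = 6.36e-06, and adjusted p = 0.548 with an estimated correlation), and at ZT14 of -0.25 (camera adjusted p = 2.81e-05, and adjusted p = 0.584 with an estimated correlation). Their mean by library at ZT2 was 0.24, 0.23 and 0.55 in TG and 0.02, 0.23 and -0.25 in WT, so the groups touched. At ZT14 it was -0.33, -0.25 and -0.38 in TG and -0.10, 0.10 and 0.01 in WT. Adjusted over the list alone, 0 members passed at ZT2 by edgeR, and 1 was higher and 3 lower at ZT14, where Gpam, the first enzyme of glycerolipid synthesis, had a log2 fold change of -0.57 (SE 0.13). The 26 interferon response genes had a median of 0.32 at ZT14 (camera adjusted p = 2.77e-10, and adjusted p = 0.584 with an estimated correlation), with 4 higher and 0 lower adjusted over the list alone. In the same libraries the 30 acute phase genes had a median of 0.35 (camera adjusted p = 8.52e-07, and adjusted p = 0.594 with an estimated correlation), against -0.28 at ZT2 (camera adjusted p = 0.00622, and adjusted p = 0.774 with an estimated correlation). Their mean was 0.43, 0.07 and 0.58 in the TG libraries at ZT14. At ZT2 it was -0.07, -0.16 and -0.47 in TG and 0.25, -0.43 and 0.18 in WT, so the groups overlapped. At ZT14 8 erythroid genes had a median of 0.73 (camera adjusted p = 0.00136, and adjusted p = 0.584 with an estimated correlation). The 34 genes of oxidative phosphorylation had a median of -0.15 at ZT14 (camera adjusted p = 1.82e-08, and adjusted p = 0.595 with an estimated correlation), but their mean against WT was -0.40 in TG at ZT14 replicate 1 and -0.01 and -0.13 in replicates 2 and 3.

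Genes with higher expression in female than in male liver had a median log2 fold change of 0.41 over 21 members at ZT2 (camera adjusted p = 6.31e-06, and adjusted p = 0.591 with an estimated correlation), and 34 genes with higher expression in males one of -0.30 (camera adjusted p = 6.31e-06, and adjusted p = 0.745 with an estimated correlation). Adjusted over the list alone, 2 female-biased and 0 male-biased members passed at ZT2. These values moved with 2 libraries. Against the WT mean of the same time, the female-biased mean lay at 1.35 in TG at ZT2 replicate 2 and 1.14 in TG at ZT14 replicate 3, and at 0.00, 0.69, 0.07 and 0.24 in TG at ZT2 replicates 1 and 3 and TG at ZT14 replicates 1 and 2. Across the 5 planned contrasts, camera called 11, 18, 16, 10 and 9 of the 37 lists with the preset correlation (TG against WT at ZT2, at ZT14, time in WT, time in TG, interaction), and 0, 0, 1, 0 and 0 with an estimated correlation. Fry called 0, 0, 11, 11 and 0 lists in 1 direction, and 2, 0, 23, 27 and 2 in either direction.

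Time of day changed far more genes than genotype. In WT livers 1398 genes differed between ZT14 and ZT2, 739 higher and 659 lower at ZT14. Among clock genes, Ciart, a repressor of the clock, rose 63.7-fold, Per3 rose 32.8-fold from 1.23 ± 0.583 to 39.0 ± 9.71 CPM (SD, n = 3 each) and Per2 5.69-fold. Npas2 fell from 8.04 ± 0.788 to 0.483 ± 0.160 CPM. Arntl, which encodes BMAL1, fell 2.33-fold. All 3 PAR bZIP genes rose, Dbp 5.23-fold, Tef 3.31-fold and Hlf 2.10-fold. Of the 19 core clock genes, 8 rose, 4 fell and 7 did not pass, and adjusted over the list alone 9 rose and 5 fell. Without WT at ZT2 replicate 2 the log2 fold changes of Ciart and Dbp went from 5.99 to 6.89 and from 2.39 to 3.06, and Dbp stood at 1.86 without WT at ZT2 replicate 1. Per3 went from 5.03 to 3.86 with uniquely mapped reads, and Per2 from 2.51 to 3.79 with exon reads alone.

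Of 22 genes of fatty acid synthesis 16 rose in WT, 0 fell and 6 did not pass, with a median log2 fold change of 1.00, and adjusted over the list alone 18 rose and 1 fell. Thrsp, a regulator of lipogenesis, rose from 86.6 ± 38.0 to 1628 ± 213 CPM, Srebf1, the lipogenic transcription factor, 3.95-fold, Elovl6, a fatty acid elongase, 4.43-fold, and Pnpla3, a lipid droplet lipase, 22.0-fold (n = 3 each). This was the only list of the 37 that held in camera with an estimated correlation (camera adjusted p = 3.79e-24, and adjusted p = 0.031 with an estimated correlation). Of 25 cholesterol synthesis genes 6 rose, 0 fell and 19 did not pass, or 11 and 0 adjusted over the list alone (camera adjusted p = 1.01e-07, and adjusted p = 0.455 with an estimated correlation). Among D-box output genes, 4 of 14 rose and 0 fell, or 6 and 0 adjusted over the list alone (camera adjusted p = 1.89e-05, and adjusted p = 0.0753 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 5.16-fold and Por, the electron donor of cytochromes P450, 3.10-fold.

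Of 19 heat shock genes 11 rose at ZT14 in WT and 0 fell, or 14 and 0 adjusted over the list alone (camera adjusted p = 7.8e-12, and adjusted p = 0.185 with an estimated correlation). Bag3, a cochaperone, rose 2.41-fold and Hspa8, the constitutive HSP70, 1.86-fold. Of 30 acute phase genes 7 fell, 1 rose and 22 did not pass, or 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00039, and adjusted p = 0.48 with an estimated correlation). The fibrinogen genes Fga and Fgg fell 2.46-fold and 2.45-fold. Elovl3, a fatty acid elongase, fell from 599 ± 73.1 to 77.9 ± 39.7 CPM and Crot, a peroxisomal acyltransferase, from 791 ± 25.0 to 188 ± 17.8 CPM. Egr1, an immediate early gene, fell from 56.0 ± 33.4 to 3.44 ± 1.35 CPM.

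By edgeR's quasi-likelihood test, time in WT gave log2 fold changes of 5.03 (SE 0.31, adjusted p = 1.55e-06) for Per3, -4.05 (SE 0.25, adjusted p = 1.55e-06) for Npas2, 4.23 (SE 0.42, adjusted p = 8.48e-05) for Thrsp and -2.94 (SE 0.36, adjusted p = 0.000372) for Elovl3. Npas2 ran from -5.47 to -3.79 over the alternatives. With library size alone in place of TMM, 1022 genes were higher and 498 lower, which moved the share of higher calls from 52.9% to 67.2%. The count was 924, 770 and 880 without WT at ZT2 replicate 1, WT at ZT14 replicate 1 and WT at ZT14 replicate 3.

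In TG livers 1862 genes differed between the times, 1021 higher and 841 lower at ZT14. Among clock genes, Ciart rose 67.0-fold, Per3 54.1-fold and Per2 5.56-fold. Npas2 fell from 16.1 ± 0.849 to 0.0870 ± 0.0798 CPM (SD, n = 3 each) and Arntl fell 4.07-fold. All 3 PAR bZIP genes rose, Dbp 17.4-fold, Tef 4.16-fold and Hlf 2.03-fold. Of 19 core clock genes 9 rose and 5 fell, and adjusted over the list alone 9 and 6 (camera adjusted p = 0.00164, and adjusted p = 0.367 with an estimated correlation). With uniquely mapped reads the log2 fold changes of Ciart and Per3 went from 6.07 to 5.20 and from 5.76 to 4.40. Per2 went from 2.47 to 3.59 with exon reads alone, and Npas2 from -7.48 to -8.42 without TG at ZT14 replicate 1. Elovl3 fell from 505 ± 42.9 to 19.5 ± 6.59 CPM and Rnf125, a ubiquitin ligase, from 178 ± 30.5 to 18.2 ± 0.337 CPM.

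Of 31 ribosome biogenesis genes, 17 rose at ZT14 in TG and 0 fell, or 21 and 0 adjusted over the list alone, against 7 and 0, or 9 and 1 adjusted over the list alone, in WT. Nop2, a nucleolar methyltransferase, rose 2.26-fold and Polr1a, the largest subunit of RNA polymerase I, 1.85-fold in TG. Camera gave the list an adjusted p = 1.49e-11 in TG, and adjusted p = 0.268 with an estimated correlation, and in WT 0.000222, and adjusted p = 0.48 with an estimated correlation. For the interaction, which tests this difference, edgeR called 0 members over all genes and 0 adjusted over the list alone (camera adjusted p = 1.44e-05, and adjusted p = 0.542 with an estimated correlation). Of 19 heat shock genes 10 rose and 0 fell in TG, or 13 and 1 adjusted over the list alone (camera adjusted p = 6.3e-11, and adjusted p = 0.268 with an estimated correlation), with Hspa1b, an inducible HSP70, up 11.5-fold. Of 22 genes of fatty acid synthesis 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 2.3e-06, and adjusted p = 0.268 with an estimated correlation), with Thrsp up 6.17-fold and Srebf1 2.28-fold.

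By edgeR's quasi-likelihood test, time in TG gave log2 fold changes of 5.76 (SE 0.34, adjusted p = 1.71e-06) for Per3, -7.48 (SE 0.31, adjusted p = 7.34e-08) for Npas2, 4.12 (SE 0.53, adjusted p = 0.000465) for Dbp and 1.18 (SE 0.12, adjusted p = 7.7e-05) for Nop2. With library size alone 1265 genes were higher and 685 lower, which moved the share of higher calls from 54.8% to 64.9%. The count was 1223, 1127 and 1230 without TG at ZT2 replicate 2, TG at ZT2 replicate 3 and TG at ZT14 replicate 1, and 1150 without the 2 libraries that stood apart.

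**Figure D4:**
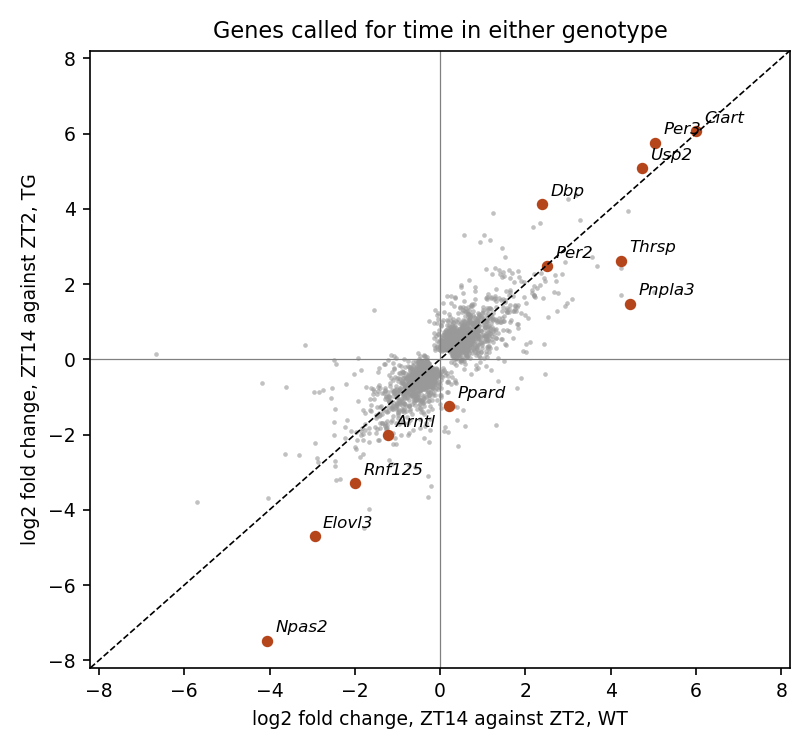
Log2 fold change of ZT14 against ZT2 in WT (x axis) and TG (y axis) for the genes called in either genotype, with the diagonal dashed and genes named in red. Of 2364 genes, 95.6% had the same sign in both genotypes.

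Of the genes called in either, 2364 in all, 95.6% had the same sign in both. In both genotypes 472 higher genes and 424 lower genes were called, where independent lists would share 49.5 and 36.4, and 0 were called in opposite directions by edgeR. Pearson's r of the log2 fold changes was 0.81 across these genes and 0.60 across all 15244, across genes, which are not independent replicates. These comparisons use no library in common.

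Ppard was the only gene whose time difference depended on genotype by edgeR's quasi-likelihood test. It went from 17.3 ± 1.24 CPM at ZT2 to 20.2 ± 2.04 CPM at ZT14 in WT, and from 39.4 ± 5.75 to 16.7 ± 0.0623 CPM in TG (SD, n = 3 each), an interaction of -1.46 on the log2 scale (SE 0.16, adjusted p = 0.0109 by edgeR). Npas2 followed with -3.43 (SE 0.49, adjusted p = 0.0519, called without WT at ZT14 replicate 2 or TG at ZT14 replicate 1, at the lowest 0.0193, and by DESeq2) and Cadm3 with 3.55 (SE 0.50, adjusted p = 0.0519, and 0.0162 without TG at ZT14 replicate 3), and 912 genes lay below an unadjusted p of 0.05. Nat8f6 averaged 4.09 CPM in WT and 4.19 CPM in TG at ZT2, and 31.1 and 11.3 CPM at ZT14, with an interaction of -1.50 (SE 0.28, adjusted p = 0.283). Of 22 fatty acid synthesis genes, 0 passed over all genes by edgeR and 8 were lower adjusted over the list alone, with a median of -0.53 (camera adjusted p = 1.03e-11, and adjusted p = 0.317 with an estimated correlation). The 19 core clock genes had 1 higher and 1 lower adjusted over the list alone, and fry for either direction gave adjusted p = 0.00192, against 0.734 for fry in 1 direction and camera adjusted p = 0.128 (adjusted p = 0.735 with an estimated correlation). Over all lists edgeR called 0 members, 81 members lay below an unadjusted p of 0.05, DESeq2 called 5 and limma-voom 0. The Ppard call was lost without TG at ZT2 replicate 2, WT at ZT14 replicate 3 or TG at ZT14 replicate 2, with adjusted p = 0.0533 to 0.0609 by edgeR, and without both libraries that stood apart. DESeq2 called 21 interaction genes, and edgeR 11 without a filter beyond 1 read, 4 with RLE size factors and 4 with uniquely mapped reads. The count was 2 or 3 without any 1 of WT at ZT2 replicates 2 and 3, WT at ZT14 replicates 1 and 2 and TG at ZT14 replicates 1 and 3.

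**Figure D5:**
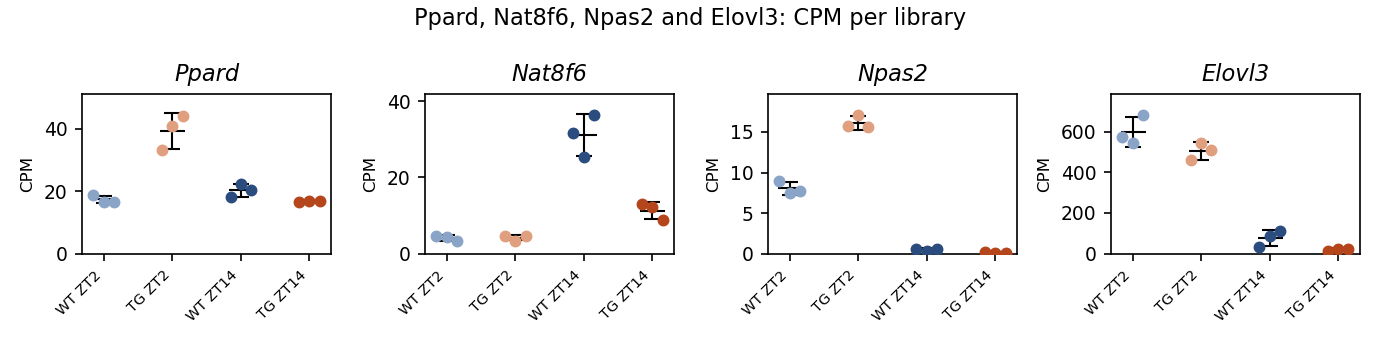
CPM (y axis) of Ppard, Nat8f6, Npas2 and Elovl3 in each library of the 4 groups (x axis), with the mean and SD of 3 libraries as bars. Ppard averages 39.4 CPM in TG at ZT2 and 16.7 to 20.2 CPM in the other groups.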

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

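All tests in this part except the counts over other splits of the samples were chosen after the results were seen. Ppard stands out because its time difference depended on genotype, by -1.46 on the log2 scale, as given above. The real labels called 1 gene for this interaction. Of 100 relabellings of genotype within each time (of 200 possible), 8, the real one among them, called as many or more. Chance cannot be excluded for that count. The highest other relabelling called 22, and it is the one that swaps the genotypes at ZT14 only. That swap turns the genotype difference shared by both times into an interaction. The remaining ones reached 2, but those that exchange more libraries at 1 time than at the other do the same in part. The relabellings are therefore not a clean measure of chance for the interaction and cannot decide it. The mean of both times is a contrast added after the data were seen. For it 1 of 100 relabellings, the real one, gave as many as 22 genes, and the highest other gave 2. This argues against chance for that count among these libraries. It cannot speak for animals if the samples of a group are not separate animals. Reads in introns, a column the comparisons did not test on its own, stood above every WT library in all 6 TG libraries for Gpr137, Bad and Rps6ka4, with log2 fold changes of 3.77, 1.59 and 1.52 for the mean of both times (edgeR adjusted p = 1.47e-08, 0.00145 and 0.0191). Uniquely mapped intron reads of Gpr137, scaled to library size as CPM, were 26.3 to 47.7 in TG and 2.02 to 3.09 in WT, against a log2 fold change of 1.42 for its uniquely mapped exon reads. For Bad the gap was narrow, at 4.48 in the lowest TG library against 3.88 in the highest WT library. For Rps6ka4 it was slight and at low counts, at 0.9495 against 0.9294.

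The first pattern is the stretch of chromosome 19 that holds 7 of the 22 genes called for the mean of both times. Reads shared between gene copies are argued against, since all 7 remained called with uniquely mapped reads, and so is a chance scatter of calls, since 10000 random placements never put more than 3 calls in 200 kb (permutation p = 0.0001, the smallest they can give). The loss of 1 of 2 copies of Prdx5, Trmt112 and Esrra stays open: the 95% intervals of all 3 log2 fold changes hold -1, at -1.34 to -0.97, -1.29 to -0.95 and -1.14 to -0.84. A response to E4BP4 itself cannot be told apart from an effect of where the transgene lies, because Nfil3 and Gpr137 both exceed every WT library in 6 of 6 TG libraries and no liver has one without the other. A candidate explanation is that a DNA change carried with the transgene, such as its insertion there, alters this stretch, and DNA at this site was not analysed here.

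The second pattern is the pair of libraries set apart, TG at ZT2 replicate 2 and TG at ZT14 replicate 3, in which the 20 tested Mup genes, male-biased urinary proteins of near-identical copies, summed to 24310 and 16080 CPM against 45880 to 80680 CPM in the other 10 libraries. Wild-type liver under a TG label is argued against, since at least 6 of the 7 called chromosome 19 genes lay beyond all 6 WT libraries in each (all 7 had been predicted, so this threshold was relaxed after the values were seen; Gpr137 was at 59.5 and 59.8 CPM against at most 19.8 in WT), and so is female liver, since the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to at least 103.5% of the lowest other library. A lower share of hepatocytes was predicted to raise markers of all other cells alike, but endothelial markers moved by 0.05 and -0.04 on the log2 scale and lymphocyte markers by 0.76 and 0.47. Such unlike shifts also occurred in libraries not set apart. Cholangiocyte and endothelial markers lay at 0.43 and 0.03 in WT at ZT2 replicate 3, and at 0.63 and 0.05 in TG at ZT2 replicate 1. The markers therefore cannot decide whether the share of hepatocytes was lower. In the 2 libraries set apart, periportal markers lay at 0.69 and 0.69, pericentral markers at -0.52 and -0.58, and male-biased genes at -1.09 and -1.15. What set these livers apart stays open, and a biological difference such as hormonal state was not tested.

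The third pattern is the kind of Nfil3 reads in TG. Exon reads had a log2 fold change of 1.17 for the mean of both times (95% interval 0.90 to 1.44), and intron reads one of -0.07 (-0.38 to 0.24). An extra copy without introns fits these values, since the upper limit of 0.24 for intron reads lies below the rise in exon reads. Reads from another gene copy are argued against, since every Nfil3 read in the 12 libraries was uniquely mapped, with a log2 fold change of 1.07. At ZT2 and ZT14 apart, intron reads stood at 0.30 and -0.44 and reads across exon junctions at 0.47 and -0.69 (mean -0.11, -0.70 to 0.49), so the structure of the added transcript stays open.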

How the results depend on the processing

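Exon reads alone and the omission of the 2 libraries set apart were chosen after the data were seen. Over the alternatives, in a selection of genes wider than those named in the text, 3969 values kept their direction and side of the threshold, 197 fell short of it, 71 newly passed it and 0 reversed; for lists, 930 kept both and 99 fell short. That selection was made after their values were seen, so over all genes the rule takes, 0 of 6448 values of called genes and 249 of 19998 values of uncalled genes changed sign. These gene totals include settings that changed only the threshold, an adjusted p of 0.01 and an absolute log2 fold change of at least 1. In those settings no sign can change, so the totals overstate how often the direction was put to a test. In addition, the rule took many called genes only where replicates did not overlap between the groups. For those genes, leaving out libraries could hardly change a sign, so the 0 among called genes was largely fixed in advance. Where a cause is not given, the cause was not tested. DESeq2 called 57 genes at ZT2, 53 at ZT14, 21 for the interaction and 75 for the mean of both times, with 9 shared higher genes. Without a filter beyond 1 read these were 43, 41, 11, 61 and 9. The interaction count was 4 with RLE size factors, 4 with uniquely mapped reads, and 2 without the 2 libraries set apart, where time in TG gave 1150, the mean 12 and the interaction 20 lists. Fits to the 6 samples of a contrast shared 2 higher genes. At an adjusted p of 0.01, by construction fewer passed, with 606 for time in WT, 757 for time in TG, 0 for the interaction (912 below an unadjusted p of 0.05 by edgeR, DESeq2 21 and limma-voom 1 at 0.05), 12 for the mean and 2 shared higher genes, and with an absolute log2 fold change of at least 1 the counts were 374 and 443 for time and 13 for the mean. Camera with an estimated correlation called 0, 0, 1, 0 and 0 lists in the 5 planned contrasts, whereas fry called 0, 0, 11, 11 and 0 in 1 direction and 2, 0, 23, 27 and 2 in either direction, in the order TG against WT at ZT2, at ZT14, time in WT, time in TG and interaction. DESeq2 has no list test. Leaving out each library in turn gave 7 to 22 genes at ZT2, 10 to 17 at ZT14, 770 to 1511 for time in WT, 1127 to 1873 for time in TG, 0 to 3 for the interaction and 13 to 25 for the mean, with 2 to 5 shared higher and 3 to 4 shared lower genes, and 9 to 17, 13 to 22, 13 to 18, 9 to 15 and 7 to 18 lists. Of the calls, 6 of 11, 10 of 13, 630 of 1398, 822 of 1862, 0 of 1 and 13 of 22 held in all 12 such fits. Samples with the same replicate number share only a number: their deviations correlated at -0.253 to 0.154, with 2 of 18 above 0.1, and a replicate block gave 12, 14, 1370, 1829, 2 and 18 genes. At this depth the interaction test recovered 34% of simulated 2-fold changes, 72% of 4-fold changes and 86% of 8-fold changes, in a simulation that may overstate recovery. Real interactions of any of these sizes may therefore be missed, as may smaller ones.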

Other observations

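The lists and genes of this part were picked for the text after the results were seen, whereas the list tests and the splits of the samples were planned. In WT, 5 of 26 interferon response genes were lower at ZT14 and 0 higher, or 9 and 0 adjusted over the list alone, with Ifi47, an interferon-induced GTPase, at a log2 fold change of -1.92 (SE 0.25, edgeR adjusted p = 0.000496, n = 3 each) and Rsad2, an antiviral enzyme, at -1.58 (SE 0.27, adjusted p = 0.0027); camera gave the list adjusted p = 1.63e-05, and adjusted p = 0.455 with an estimated correlation. Of 16 glycolysis genes 6 were higher and 1 lower in WT, and 7 higher and 0 lower in TG, with 9 not past in each (9 and 1, and 9 and 0, adjusted over the list alone). Camera gave this list adjusted p = 8.89e-07 in WT and 0.00164 in TG, and adjusted p = 0.185 and 0.451 with an estimated correlation. Gys2, the liver glycogen synthase, rose by 1.20 (SE 0.15, adjusted p = 0.000454) in WT and 1.33 (SE 0.15, adjusted p = 0.000212) in TG. In TG, 2 of 20 NRF2 targets were lower at ZT14 and 0 higher, and the same adjusted over the list alone (camera adjusted p = 0.0324, and adjusted p = 0.451 with an estimated correlation). These were Gclc and Osgin1, at -0.98 (SE 0.13, adjusted p = 0.000583) and -1.73 (SE 0.32, adjusted p = 0.00439).

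Splits of 6 samples into 3 and 3 number 10, too few for a share under 0.05. With the real split, 11 genes were called at ZT2, 13 at ZT14, 1398 for time in WT and 1862 for time in TG, each reached by 1 of 10 splits, and the highest other splits called 0, 1, 23 and 0. Camera with the preset correlation called as many lists as the real split in 9, 1, 4 and 9 of 10 splits, with 11, 18, 16 and 10 lists for the real one and up to 20, 17, 21 and 25 for another. For the interaction, 76 of 100 relabellings called 9 lists or more, as many as the real labels, with up to 25, so chance cannot be excluded for the number of lists. Some of these relabellings carry part of the genotype difference into the interaction, so they are not a clean measure of chance. In every comparison but TG against WT at ZT14, some other split called more lists than the real one. Even the lowest other splits called 8, 8, 4 and 2 lists. Camera adjusted p-values with the preset correlation therefore overstate the evidence for a list in these data. With an estimated correlation, the real labels gave 0, 0, 1 and 0 lists in these 4 comparisons. What makes the other splits call lists was not tested further.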
